A study of Lactobacillus delbrueckii subsp. bulgaricus and Lactobacillus delbrueckii subsp. bulgaricus
Saccharomyces cerevisiae with 4 samples.

How the data were processed

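Each of the 4 samples of the series is a set of arrays of the same dye orientation, per the labels: 2 samples of the chemostat experiment with 4 arrays each and 2 of the batch control with 2 arrays each. Per the labels' protocols, samples were quenched in liquid nitrogen, total RNA was isolated with mechanical lysis by zirconium beads, and every RNA sample was divided and labelled with both dyes, Cy3 and Cy5. The scanner files were deposited as spot intensity, with mean foreground and mean local background brightness for each dye on a linear scale and no background correction, per the file headers. Scanner, image software and their settings are not given in the sources used here. Each spot also carries a deposited flag with the codes 0, 2 and 3, the same in both channels; the meaning of the codes is not stated in the files. By the values, code 2 marks spots close to their background. Flagged spots were kept.

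The authors' deposited value table holds log ratios, assumed to be log10, with 1 value per gene copied to all its probes. The values are identical, within 4.6e-06, in both dye orientations. Values cited here from the table were not converted to another base. Its values run as mono over mixed culture: over the 510 brightest features with a value their correlation with the log2 ratios of mixed over mono culture from the scanner files was −0.949, with a slope of −0.397 per log2 unit. The base of the logarithm and the centring are not stated, and the control columns followed the scanner values too weakly (correlation −0.400) to settle either. The column medians are −0.065 in the chemostat columns and 0.020 in the control columns. For 4 features, groEL among them, no value of this table was used here. The table served as an alternative, not for the main values. The amount of yeast RNA added in the control is not given in the sources used here.

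Spot intensities were processed with limma 3.58.1 in R 4.3.3. Background was corrected with normexp and an offset of 50, and log2 ratios of Cy5 over Cy3 were normalised within each array by loess, with the array maker's control spots at weight 0. Of 15744 spots, 15208 belonged to 7401 probes of the bacterium and 536 were control spots, which were left out afterwards. Values were averaged over the 2 or 3 spots of a probe and then over the 1 to 5 probes of a feature. Gene symbols were taken from the probe names; 1456 annotated loci have none there and are not named except by identifier. A feature was taken as above background in a channel where at least 1 of its probes exceeded the mean of the 77 negative control spots by 2 SD. For a feature not above background in a culture on any array, the fold is given as a bound, from channel levels after loess and Aquantile normalisation, as the bright channel's mean against the higher of the dim channel's value and the lowest level above background on each array. The arrays carry foreground signals near background on many spots (41.9% to 63.3% with code 2 on the chemostat arrays), and their number limits the precision.

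The chemostat effect was fitted on 8 arrays and the control effect on 4, each array being an observation, with a gene-specific dye term and the dye orientation coded as +1 or −1. The difference of both effects was fitted on all 12 arrays, with 1 spread and 1 dye term per feature shared by both experiments. Tests were two-sided, by lmFit and eBayes, with Benjamini-Hochberg adjustment over the 2057 features and a threshold of 0.05. Standard errors are those of the moderated fit. Log2 ratios and signs given for single arrays are dye-corrected, with the fitted dye term of the gene subtracted. Correlations between arrays use ratios without this correction. Gene lists were fixed by symbol before the data were examined, 21 in all. Of these, 8 had at least 3 members with a symbol and were tested with camera (preset correlation 0.01), with camera and an estimated correlation, and with fry; the other 13 were not tested.

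The genes named in the text follow a rule set before the data were examined. Among features with an adjusted p below 0.05, the same dye-corrected sign on all 8 arrays, no call of the same direction in the control and a symbol, it takes the 12 largest rises and 12 largest falls, or all where fewer pass. From the control it takes up to 5 calls in each direction. From each list it takes up to 4 members with the smallest adjusted p, together with lac, gal and carbamoyl-phosphate synthase genes at any p. Loci outside this rule are named as such.

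The fits were tested on simulated arrays with the spread of the real features, 200 of 2057 features changed and 20 simulations. For the chemostat comparison, 61.3% of features changed by 0.5 on the log2 scale, 92.3% of those changed by 1 and 98.3% of those changed by 2 were called, and 4.74% of calls were unchanged features. For the control these shares were 62.8%, 90.5%, 98.9% and 4.37%, and for the difference 26.4%, 77.6%, 96.9% and 2.58%. The arrays were simulated as independent, and the adjustment depends on how many features change, so these shares need not hold for the real arrays. In the real control 12 features had a log2 ratio of at least 0.5, and 3 features were called. With no change and arrays correlated within sets at 0.437, the chemostat fit on 2057 features called a median of 1 and at most 12 features, and the fit with sets as a random block at most 2. All simulations drew the features independently of each other, and this one gave every set the same correlation. These counts are therefore no upper bound for false calls on the real arrays. A simulated shift of −0.3 in the 49 ribosomal protein genes was called by camera in 20 of 20 simulations, with 3 calls in all among the other 7 lists.

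The alternatives tried were other background corrections, median centring, scaling between arrays, a filter on dim probes, no dye term, the median over probes, arrays averaged per sample, sample as a random block, a joint fit, robust moderation, a minimum fold of 2, the authors' table, and leaving out single arrays or samples. Alternatives added later are named in the closing section. The set of correlated arrays was found by average linkage of their log ratios at a mean correlation of 0.5. Statmod 1.5.0 served for the random block.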

Results

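The series measured transcript levels of Lactobacillus delbrueckii subsp. bulgaricus, a lactic acid bacterium used in yoghurt making, with custom DNA microarrays hybridised with 2 dyes. In the chemostat experiment, RNA of the bacterium grown alone (mono culture) was set on each array against RNA of a culture grown together with the yeast Saccharomyces cerevisiae (mixed culture). A chemostat is a continuously fed culture held at a constant growth rate; here it was anaerobic and limited by lactose. In the control experiment, RNA of batch cultures of the bacterium was set against the same kind of RNA to which yeast RNA had been added, so that binding of yeast RNA to the bacterial probes could be measured. The chemostat experiment comprised 8 arrays, 4 with the mixed culture RNA in Cy5 and 4 with it in Cy3. The control comprised 4 arrays, 2 in each orientation. Arrays are numbered 1 to 8 and 1 to 4 in the order of the deposited files. The labels do not say how many cultures were grown or which arrays share an RNA extract, and the amount of yeast RNA is not given either. Per the protocols every RNA sample was labelled with both dyes. Arrays of opposite orientation are therefore likely to share RNA samples, and the arrays are not all independent. The p-values measure the spread between arrays, which is then in part technical, and not the spread between cultures.

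The arrays carried 2057 features, of which 1626 were annotated loci and 431 were predicted open reading frames outside the annotation. A gene symbol was given for 170 loci. On the chemostat arrays, 60.9% to 74.5% of the features lay above background in the mono culture channel. In the mixed culture channel the share was 62.7% to 77.5% on chemostat arrays 2, 4, 5, 6 and 8, and 90.1%, 96.5% and 94.3% on chemostat arrays 1, 3 and 7. On the control arrays it was 43.9% to 59.2% without yeast RNA and 47.7% to 61.6% with it.

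The first comparison asked which transcripts of the bacterium differed when it grew together with yeast. In mixed culture, acpP (LBUL_0819), which encodes an acyl carrier protein of fatty acid synthesis, had the largest rise among loci with a symbol, 3.74-fold (log2 ratio 1.90 ± 0.16, SE, n = 8 arrays; limma adjusted p = 0.00035). The dehydratase gene fabZ of the same pathway rose 2.16-fold (log2 1.11 ± 0.23, adjusted p = 0.014). The largest fall among loci with a symbol was that of groEL, which encodes a chaperonin. It was 2.39-fold lower in mixed culture (log2 −1.26 ± 0.27, adjusted p = 0.017); with no background correction it had −0.76 and was not called (adjusted p = 0.062). Of the 31 falls of at least 2-fold, groEL was the only 1 at a locus with a symbol. Among loci with a symbol, ribosomal proteins made up 7 of the next 11 falls that the fixed rule selected. Of all 170 loci with a symbol, 49 were ribosomal protein genes.

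In all, 279 of 2057 features changed at an adjusted p below 0.05, 110 of them higher and 169 lower in mixed culture. At least 2-fold changes numbered 22 higher and 31 lower. Of the 279 features, 226 had a dye-corrected log ratio of the same sign on all 8 arrays. Among the loci with a symbol, 9 rose and 24 fell. For 17 of the called features the mono culture signal, and for 1 the mixed culture signal, was not above background on any of the 8 arrays. The count was 67 (27 higher, 40 lower), all of them among the 279, when correlated arrays were treated as a random block, and 138 without chemostat arrays 1, 3 and 7. It was 143, 168 and 172 without chemostat array 3, 6 or 8, respectively, and without array 1 the number of rises was 72. With arrays averaged per sample or with the sample as a random block, more features rose than fell.

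**Figure D1:**
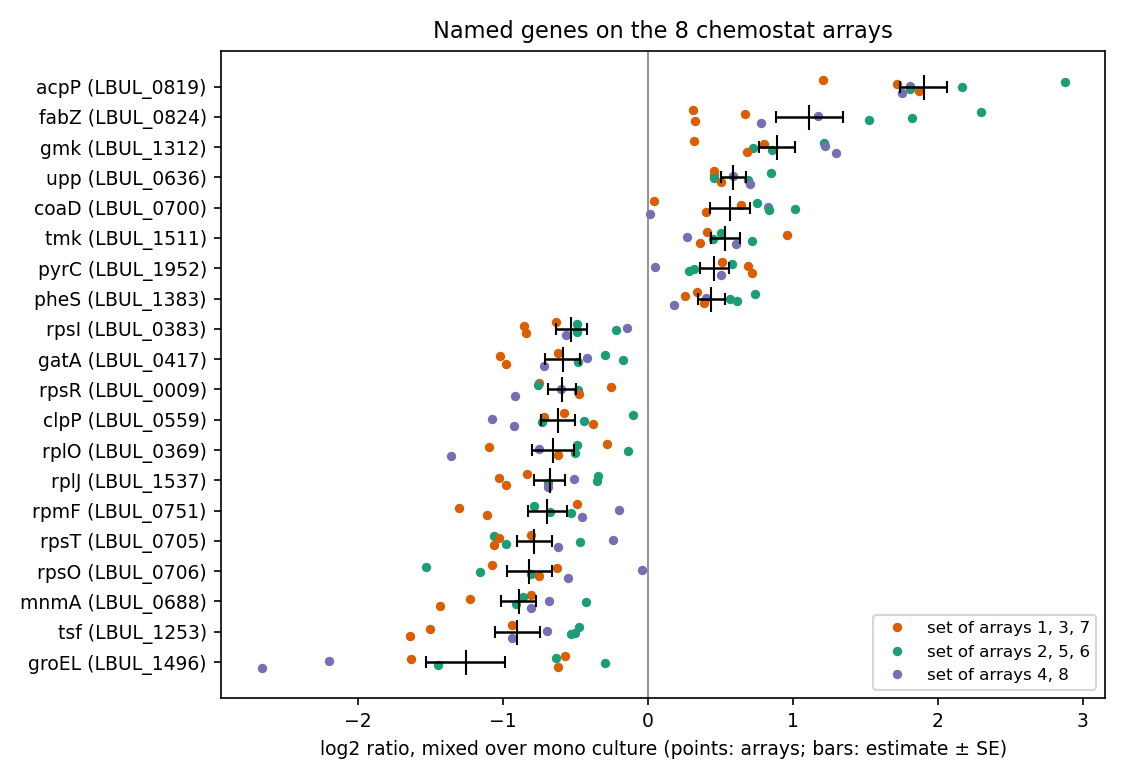
Log2 ratio of mixed over mono culture (x axis) for the 8 rising and 12 falling genes selected by the fixed rule (y axis). Each point is the dye-corrected value on 1 of the 8 arrays, coloured by the sets of correlated arrays, and the black bars give the fitted estimate ± SE. On every array acpP lies between 1.21 and 2.87, and groEL between −2.66 and −0.29.

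Besides acpP and fabZ, 6 genes with a symbol met the rule for rises. Guanylate kinase, gmk, rose 1.85-fold (log2 0.89 ± 0.13, adjusted p = 0.0026); when arrays were centred on their median in place of loess it had 0.37 and was not called (adjusted p = 0.26). The uracil salvage enzyme gene upp rose by a log2 ratio of 0.59 ± 0.09 (adjusted p = 0.0029), but had −0.0123 with median centring. The thymidylate kinase gene tmk had a log2 ratio of 0.53 ± 0.10 and pheS, a subunit of phenylalanyl-tRNA synthetase, one of 0.44 ± 0.09, which was 0.10 with median centring (adjusted p = 0.58). The value of coaD, a gene of coenzyme A synthesis, was 0.57 ± 0.14 in the chemostat and 0.46 ± 0.09 in the yeast RNA control, where it was not called (adjusted p = 0.26). With the median over probes in place of the mean, the chemostat value of coaD was 0.20 (adjusted p = 0.30), and with background subtraction and a floor it was 0.71 (adjusted p = 0.066). The dihydroorotase gene pyrC rose by a log2 ratio of 0.46 ± 0.10, with its mono culture signal above background on 1 of 8 arrays. Of these 8 rises, acpP, fabZ, gmk and upp were still called with correlated arrays as a random block (adjusted p = 0.0045, 0.038, 0.017 and 0.030), and the other 4 were not. The call of coaD ended without chemostat array 2, 3, 5 or 6 (highest adjusted p = 0.070), that of pyrC without array 3 (0.056) and that of pheS without array 6 (0.051).

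Among the falls, tsf, which encodes a translation elongation factor, was 1.87-fold lower (log2 −0.90 ± 0.16, adjusted p = 0.0058). The tRNA modification gene mnmA was 1.86-fold lower (log2 −0.89 ± 0.12, adjusted p = 0.0019). The ribosomal protein genes rpsO, rpsT, rpmF, rplJ, rplO, rpsR and rpsI had log2 ratios of −0.82, −0.78, −0.69, −0.68, −0.65, −0.59 and −0.53; without dim probes rpmF had −0.43 and was not called (adjusted p = 0.057). The protease subunit gene clpP fell by 0.62 on the log2 scale (−0.27, adjusted p = 0.064, with no background correction) and gatA, an amidotransferase subunit gene, by 0.59. With correlated arrays as a random block, tsf, mnmA, rpsT and rplJ stayed below an adjusted p of 0.05 (0.028, 0.020, 0.039 and 0.029), and the other 8 falls did not; groEL had 0.067. The call of groEL also ended without chemostat array 3 or 6 (highest adjusted p = 0.052), and that of rplO without array 3 (0.053). Without chemostat arrays 1, 3 and 7 together, groEL, rpsO, rpmF, rplO, clpP, gatA and rpsI had log2 ratios of −1.44, −0.81, −0.52, −0.64, −0.64, −0.41 and −0.37 on the 5 arrays left and were not called (adjusted p = 0.060, 0.074, 0.055, 0.090, 0.067, 0.10 and 0.12). The rises of pyrC and pheS were then 0.34 and 0.51 and were not called either (0.16 and 0.055).

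Ribosomal protein genes as a list had a median log2 ratio of −0.21, and 39 of 49 members were below 0. The downward shift was called by camera with a preset correlation (adjusted p = 5.4e-06) but not with an estimated correlation (adjusted p = 0.27). Splits of the 8 arrays often called as many lists as the real one: 11 of 35 splits, the real one included, called at least 3. Of 49 measured members, 11 fell, 0 rose and 38 did not pass the test; 14 fell when adjusted over the list alone. The test fry, which asks whether members move one way on balance, gave an adjusted p of 0.018. The smallest adjusted p values in the list were those of rpsT, rplJ, rpsR and rpsO (0.0039, 0.0046, 0.0048 and 0.0093). In the yeast RNA control the list median was 0.01.

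Chaperone and protease genes had the lowest median of the lists, −0.62, and all 9 members were below 0. By the test over all features groEL, clpP and hslU fell, and 7 members fell when adjusted over the list alone (camera adjusted p = 0.00067; adjusted p = 0.19 with an estimated correlation; fry adjusted p = 0.0096). The subunit gene hslU of an ATP-dependent protease had −0.51 ± 0.14, a call that ended without chemostat array 1, 2, 3, 5, 6, 7 or 8 (highest adjusted p = 0.093), with sets of correlated arrays as a random block (0.18), and with no background correction (−0.16, adjusted p = 0.062). It also ended without arrays 1, 3 and 7 together (−0.27, adjusted p = 0.26) and with the median over probes (−0.47, adjusted p = 0.070). The heat shock repressor gene hrcA had −0.70 ± 0.21 and did not pass (adjusted p = 0.056), but it was called lower under 11 of the alternatives, among them median centring (−0.77, adjusted p = 0.031) and dim probes left out (−0.73, adjusted p = 0.031). The list median was −1.07 and −0.92 on chemostat arrays 4 and 8, −0.77 to −0.51 on arrays 1, 3 and 7, and −0.23 to −0.08 on arrays 2, 5 and 6. In the control it was −0.01.

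Genes of glycolysis and lactate formation had a median of −0.41, with pgi, tpiA and eno called lower out of 6 members and 4 lower when adjusted over the list alone. Glucose-6-phosphate isomerase, pgi, was 1.78-fold lower (log2 −0.83 ± 0.18, adjusted p = 0.017); tpiA had −0.61 ± 0.15 and eno −0.38 ± 0.11. The member pgk had −0.43 ± 0.13 and did not pass (adjusted p = 0.062); with median centring it had −1.14 and was called (adjusted p = 0.035). For the list, camera gave an adjusted p of 0.015, and the adjusted p was 0.39 with an estimated correlation; fry gave 0.031. Without chemostat arrays 1, 3 and 7 the list was no longer called (median −0.26, adjusted p = 0.11), nor was it without dim probes (median −0.41, adjusted p = 0.16). The single calls were not stable to leaving out arrays: pgi was lost without array 3, 6 or 8 (highest adjusted p = 0.054), and tpiA and eno were each lost without array 1, 2, 3, 6, 7 or 8 (highest adjusted p = 0.079 and 0.11). With sets of correlated arrays as a random block all 3 calls were lost (adjusted p = 0.17, 0.15 and 0.25 for pgi, tpiA and eno). They were also lost without arrays 1, 3 and 7 together, with values of −0.69, −0.36 and −0.30 (adjusted p = 0.13, 0.23 and 0.23). The call of eno further ended with background subtraction and a floor (−0.38, adjusted p = 0.12), with robust moderation (−0.38, adjusted p = 0.063) and without flag code 3 (−0.36, adjusted p = 0.051).

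Of the 4 members of the fatty acid synthesis list, acpP (LBUL_0819) and fabZ rose. A second acpP locus (LBUL_1294) had a log2 ratio of −0.31 ± 0.12 (adjusted p = 0.11) and acpS, the synthase that activates the carrier protein, −0.36 ± 0.11 (adjusted p = 0.054; −0.86, adjusted p = 0.0035, without dim probes); adjusted over the list alone, 2 members rose and 2 fell. Camera did not call the list (adjusted p = 0.53), and fry gave an adjusted p of 0.018. The median of the list was 0.40.

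Pyrimidine synthesis genes moved in both directions. Of 7 members pyrC rose, while pyrE, pyrG and carB (LBUL_0932) fell, with log2 ratios of −0.51 ± 0.13, −0.44 ± 0.12 and −0.30 ± 0.08; the counts were the same when adjusted over the list alone. A second locus named carB (LBUL_1950), like the first named for the large subunit of carbamoyl-phosphate synthase, had 0.08 ± 0.15 (adjusted p = 0.73) and lay above background in the mono culture on 2 of 8 arrays. The list median was 0.08, its mean −0.01 and the direction of the camera test down (adjusted p = 0.62), whereas fry's test for change in either direction gave an adjusted p of 1.7e-06; that test was below 0.05 for every tested list except purine synthesis. The call of carB (LBUL_0932) ended without any 1 of the 8 arrays (highest adjusted p = 0.090), that of pyrG without array 1, 2, 3, 4, 6, 7 or 8 (0.12), and that of pyrE without array 1, 3, 4, 5, 6 or 8 (0.093). The call of pyrG also ended with no background correction (−0.26, adjusted p = 0.064), with background subtraction and a floor (−0.45, adjusted p = 0.097) and with the median over probes (−0.42, adjusted p = 0.073). With sets of correlated arrays as a random block, carB (LBUL_0932), pyrG, pyrE and pyrC were not called (adjusted p = 0.21, 0.21, 0.20 and 0.13), and with median centring pyrE had −0.31 and carB (LBUL_0932) −0.14, neither of them called (0.19 and 0.35). Without arrays 1, 3 and 7 together carB (LBUL_0932) had −0.36 and pyrG −0.46, also not called (0.090 and 0.16).

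No list shift was called for purine synthesis (3 members), tRNA synthetases (15 members) or cell wall and surface genes (8 members), with camera adjusted p values of 0.53, 0.20 and 0.35 and medians of −0.11, −0.19 and −0.06. Fry's test for change in either direction gave adjusted p values of 0.58, 0.0093 and 0.018. With the preset correlation the tRNA synthetases were called lower with median centring (median −0.33, adjusted p = 0.0031) and without chemostat array 2 (−0.23, adjusted p = 0.039); with an estimated correlation neither was called (adjusted p = 0.59 and 0.58). Among their members, pheS alone was called over all features, and also alone when adjusted over each list. The members of the purine list by symbol, guaA, purH and prsA, had log2 ratios of −0.11 ± 0.10, 0.07 ± 0.08 and −0.40 ± 0.19. Among the tRNA synthetases, pheT had 0.38 ± 0.13, aspS −0.47 ± 0.14 and valS −0.47 ± 0.17. None of these 3 passed, but under other settings all were called, such as pheT with no background correction (0.28, adjusted p = 0.026), aspS with background subtraction and a floor (−0.71, adjusted p = 0.034) and valS with median centring (−0.72, adjusted p = 0.037). The cell wall genes ddl, murE, murC and murG had −0.31 ± 0.10, −0.27 ± 0.10, 0.27 ± 0.10 and −0.28 ± 0.14. On chemostat arrays 1, 3 and 7 the median of the tRNA synthetases was −0.35, −0.42 and −0.38, and on arrays 2, 5 and 6 it was 0.25, 0.14 and 0.03.

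**Figure D2:**
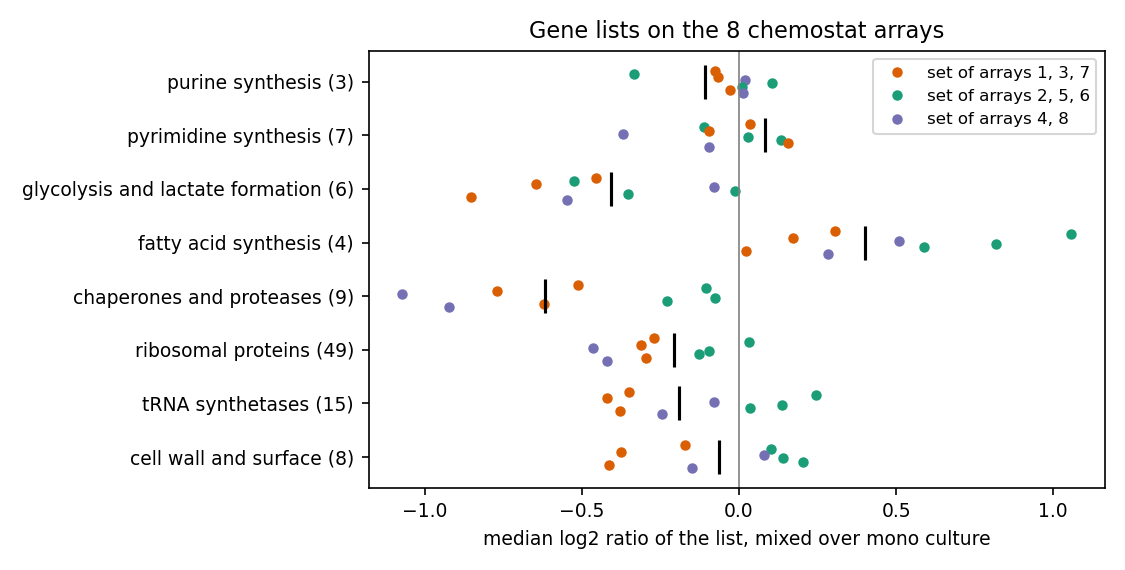
Median log2 ratio of mixed over mono culture (x axis) for each tested gene list, with the number of members in brackets (y axis). Points are dye-corrected values on the 8 chemostat arrays, coloured by set, and the black line is the median of the members' fitted ratios. The chaperone and protease list lies below 0 on all 8 arrays.

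In the lists with too few members to test, upp rose as given above, and atpC of the ATP synthase, nrdR, thyA and cysS were not called. The gene cysS encodes a tRNA synthetase, and only its symbol placed it in the amino acid synthesis list as well. The log2 ratios of atpC, nrdR, thyA and cysS were 0.30 ± 0.11, 0.0043 ± 0.17, 0.03 ± 0.13 and 0.06 ± 0.11. No locus with a lac or gal symbol was found among the probe names, so lactose and galactose genes were not analysed here. The largest fall of any annotated locus, singled out after the values were seen, was that of LBUL_0737, for which the files give no symbol. It was 8.26-fold lower in mixed culture (log2 −3.05 ± 0.37, adjusted p = 0.0013). LBUL_1668, also without a symbol, was 5.92-fold lower (log2 −2.57 ± 0.41, adjusted p = 0.0046). Their control values were 0.01 and 0.29, respectively.

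The control asked how far yeast RNA alone changes the signal of the bacterial probes. Adding yeast RNA raised 3 of 2057 features and lowered 0 by limma, with 146 features at an unadjusted p below 0.05. The ribosomal protein gene rpmG (LBUL_1547) rose 2.42-fold (log2 1.28 ± 0.10, SE, n = 4 arrays, limma adjusted p = 0.023). In the joint fit of all 12 arrays rpmG was not called (1.28 ± 0.23, limma adjusted p = 0.065). The other features were LBUL_0915 (log2 1.12 ± 0.10, adjusted p = 0.023) and LBUL_1073 (log2 1.00 ± 0.11, adjusted p = 0.044), both without a symbol. Neither was above background without yeast RNA on any of the 4 arrays, and so their rises are bounds, at least 1.73-fold and at least 1.43-fold. With the median over the probes of a gene in place of the mean, LBUL_1073 had −0.0911. With background subtraction and a floor rpmG, LBUL_0915 and LBUL_1073 had 1.45, 1.87 and 1.33, and none was called (adjusted p = 0.17, 0.17 and 0.59). Leaving out any 1 of the 4 control arrays left 1 residual degree of freedom and 0 calls, the adjusted p of the 3 features ranging from 0.0503 to 0.20. The log2 ratios then ranged from 1.19 to 1.36 for rpmG, from 1.04 to 1.21 for LBUL_0915 and from 0.88 to 1.12 for LBUL_1073. No gene list was called by camera. For the ribosomal protein list fry gave an adjusted p of 0.057, and its test for change in either direction gave 0.011.

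LBUL_0915 and LBUL_1073 were also called higher in the chemostat. LBUL_0915 was not above background in mono culture on any of the 8 arrays, and was at least 2.46-fold higher in mixed culture (limma adjusted p = 5.1e-05). LBUL_1073 had a chemostat log2 ratio of 0.61 ± 0.11, which was 0.13 with the median over probes (adjusted p = 0.41), and its call also ended with sets of correlated arrays as a random block (0.073). The overlap of 2 features compares with 0.16 for independent lists. In the chemostat rpmG had 0.40 ± 0.19 and was not called (adjusted p = 0.17). Over all features the correlation between chemostat and control log2 ratios was 0.047, a value across genes, which are not independent replicates.

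**Figure D3:**
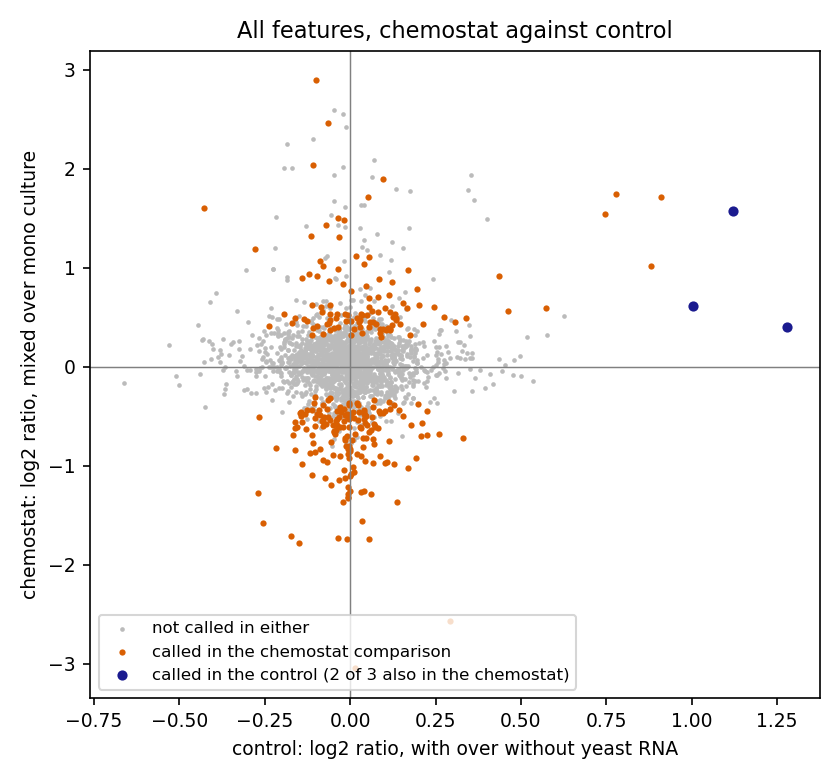
Log2 ratio of mixed over mono culture in the chemostat (y axis) against log2 ratio with over without yeast RNA in the control (x axis) for all 2057 features. Orange points are called in the chemostat comparison and large blue points in the control; the control values lie close to 0 for most chemostat calls.

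The difference between the chemostat ratio and the control ratio was tested on all 12 arrays. It was called for 58 features, 17 higher and 41 lower, all of them among the 279 chemostat calls and in the same direction. Of the loci with a symbol, 2 were higher and 4 lower, and all 6 were among the named genes. The difference was 1.81 for acpP (LBUL_0819, adjusted p = 0.0090) and 0.81 for gmk (adjusted p = 0.037). It was −0.99 for tsf (adjusted p = 0.044), −0.85 for rpsT (0.024), −0.84 for mnmA (0.030) and −0.77 for rpsR (0.014). For groEL it was −1.26 and did not pass (adjusted p = 0.13), and for fabZ it was 1.06 (adjusted p = 0.14). This fit gave all 12 arrays 1 spread per feature, so the wider chemostat scatter was also applied to the control arrays. On the control arrays groEL lay between −0.0094 and 0.011 and fabZ between −0.093 and 0.20. A missing call here therefore does not show that yeast RNA accounts for their changes. The count was 4, 14, 1 and 1 without control array 1, 2, 3 or 4, and 33 and 29 without chemostat array 3 or 6.

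Chemostat arrays differed in how alike their log ratios were. Over features, the correlation between pairs of arrays turned to the same direction ranged from 0.08 to 0.91. Grouped by these same correlations, arrays 1, 3 and 7 formed one set, arrays 2, 5 and 6 another and arrays 4 and 8 the last, each holding both dye orientations. Pairs within a set had a correlation of 0.57 to 0.91, and pairs between sets one of 0.08 to 0.53. Control pairs had 0.06 to 0.14. No feature had a dye effect at an adjusted p below 0.05 by limma (0, with 24 at an unadjusted p below 0.05).

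**Figure D4:**
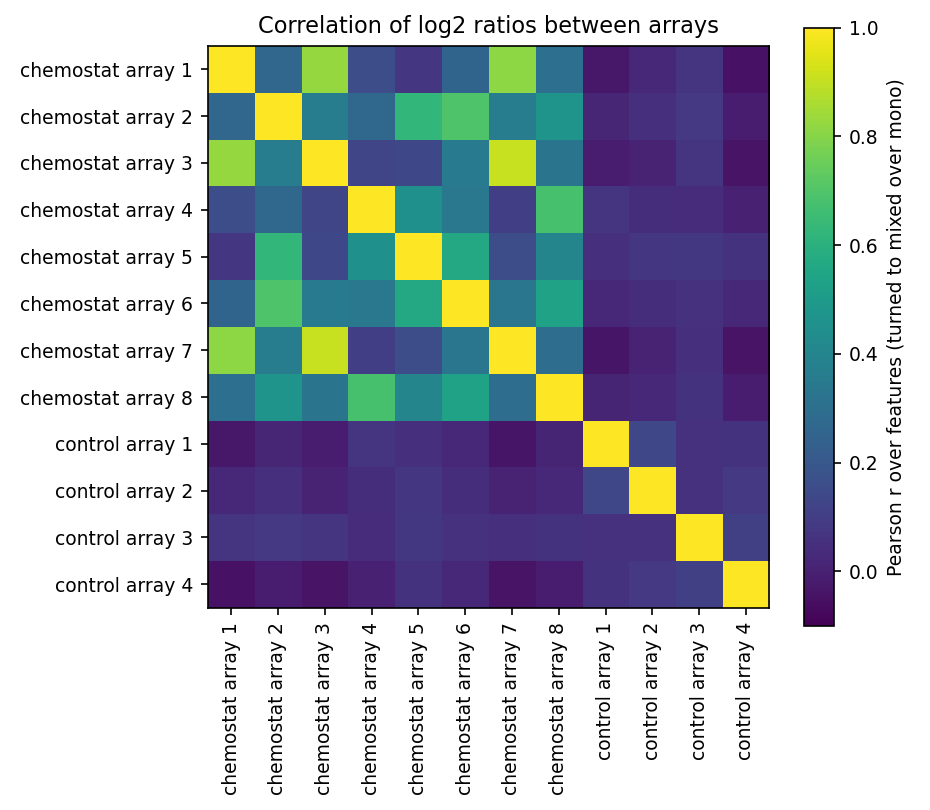
Pearson correlation over features (colour scale) between the log2 ratios of the 12 arrays, each turned to mixed over mono culture or with over without yeast RNA (both axes). Chemostat arrays 1, 3 and 7 are the most alike, with up to 0.91, and control arrays are nearly uncorrelated, at up to 0.14.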

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

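The tests of dye labelling, of the control values of the acpP region and of the share called higher among features high in the control were chosen only after the result was seen, and that last pattern and its threshold of 0.5 were picked from a plot of all features.

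Of 68 groups of values examined for a single array far from the rest, 2 stood out; chance alone gives about 1 in 20. The median of the purine synthesis list was −0.33 on chemostat array 2, and the next lowest array had −0.08. The share of spots with flag code 2 was 51.7% on control array 3, against 48.7% on the next highest array.

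The 279 features called in the chemostat comparison were set against all 35 splits of the 8 arrays into 4 and 4. Only 1 split, the real one, gave as many, and the highest other gave 0. This would exclude chance only for exchangeable arrays, and these arrays are correlated within sets. In the other splits the real difference also adds to the spread, which lowers their counts. The splits therefore do not decide whether chance explains this count. With sets of correlated arrays as a random block 67 were called. For the gene lists, 11 of the 35 splits, the real one included, called at least 3 lists by camera, with up to 5. Chance could therefore not be excluded for the number of lists. For the 58 features of the difference, 2 of 100 drawn splits of the 12 arrays into 8 and 4 gave as many, the real one included, out of 495 possible. The highest other split gave 204 and set chemostat arrays 1, 3, 4 and 7 against all others, which points to a structure among the chemostat arrays. Chance can be excluded here only for exchangeable arrays, which these are not: sets of correlated arrays as a random block left 26 calls, and leaving out 1 control array left 4, 14, 1 and 1 (arrays 1, 2, 3 and 4).

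On chemostat arrays 1, 3 and 7 the share of features above background was 25.1, 25.6 and 25.4 percentage points larger in the mixed than in the mono culture channel, against −10.3 to 8.7 points on the other 5 chemostat arrays and −0.3 to 5.2 points on the control arrays. Dye labelling is argued against, since the mixed culture RNA was in Cy5 on 1 of these arrays and in Cy3 on the other 2. Whether arrays of a set share an extract or a culture stays open: among the 514 brightest features the lowest correlation within a set exceeded the highest between sets by 0.0522, but the sets were formed from the correlations of the same arrays, so this decides nothing. Yeast RNA binding to the probes stays open too, as the 79 features higher with yeast RNA in the control at an unadjusted p below 0.05 had a median log2 ratio of 0.16 on these 3 arrays, at percentile 95.5 of 10000 lists matched on signal, and many of them may be noise. No biological explanation was tested.

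The rise of acpP and fabZ lay in a stretch of 9 consecutive loci that were all above 0 in mixed culture, 5 of them called. Binding of yeast RNA as added in the control is argued against, because the median control value of the 5 called loci was 0.0539 (SD 0.10), against 1.11 in the chemostat. The amount added is not given, so binding at another amount is not covered. The 5 loci were also chosen by their chemostat calls. The broad signal on chemostat arrays 1, 3 and 7 is argued against as well, since the median was 1.56 without these arrays and 0.55 on them. A response to growth with yeast, the difference the design names, remains open as an untested hypothesis, as do differences between cultures or extracts: the median ranged from 0.33 on array 1 to 2.30 on array 2.

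Features highest with yeast RNA in the control tended to be higher in mixed culture too. Of 12 features with a control log2 ratio of at least 0.5, 7 (58.3%) were called higher in the chemostat and 0 lower, against 5.04% of all others called higher (Fisher's exact test, two-sided, p = 6.6e-07 across features, which are not independent replicates). This is consistent with yeast RNA binding to these probes in both experiments. Without the 3 arrays with broad signal, 0 of the 7 lost over 50% of their log2 ratio (median 1.46, against 1.55 on 8 arrays). The 7 were chosen by their calls over all 8 arrays, which favours features that rise on most of them. This result therefore argues only weakly against the broad signal as the cause. The difference between chemostat and control was called for 0 of the 7 by limma. The 7 were picked for high control values, which the difference subtracts, so this count decides nothing about the cause. Their median control log2 ratio was 0.879, against 1.55 in the chemostat. Among the 22 chemostat rises of at least 2-fold, 5 belong to these features.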

How the results depend on the processing

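The alternatives chosen after seeing the data were sets of correlated arrays as a random block, spots with flag code 3 left out, annotated loci alone, and chemostat arrays 1, 3 and 7 left out. No paired analysis was possible because the replicate numbers only follow the order of the samples. A slide or scan block was not run, since no batch was found in the files, and the authors' table holds 1 value per gene, so it gives no counts of calls. The cause of the shifts below was not tested. Signal close to background limits the ratios of dim features.

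The chemostat count of 279 (110 higher, 169 lower) changed as follows, and under the alternatives not named it stayed within 1.5 times. The fits on averaged samples, with the sample as a random block and in the joint model also took in the control arrays and their spread. The count was 478 (235, 243) with median centring, where 13 of the 279 changed sign, 594 (313, 281) with arrays averaged per sample, 1053 (610, 443) with the sample as a random block, 504 (241, 263) in the joint fit, 67 (27, 40) with sets as a random block, 138 (68, 70) without chemostat arrays 1, 3 and 7, and 53 (22, 31) with at least 2-fold change. Without single arrays or samples it ranged from 0 to 305 (0 to 131 higher, 0 to 174 lower); 46 and 0 features were called without chemostat replicate 1 or 2, which leaves a single dye orientation.

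The control count of 3, all higher, was 7 with no background correction, 0 with subtraction and a floor, 9 (8 higher, 1 lower) with median centring, 7 without dim probes, 6 without a dye term, 9 with robust moderation and 5 without flag code 3; it was 0 without any single array or sample, which leaves 1 residual degree of freedom.

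The difference count of 58 (17 higher, 41 lower) was 33 (10, 23) with subtraction and a floor, 91 (26, 65) without dim probes, 307 (154, 153) with arrays averaged per sample, 214 (81, 133) with the sample as a random block, 26 (8, 18) with sets as a random block, 93 (40, 53) without chemostat arrays 1, 3 and 7, and 34 (10, 24) with at least 2-fold change; with no background correction the split was 29 and 27. Without single arrays or samples it ranged from 0 to 72 (0 to 20 higher, 0 to 52 lower).

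The number of lists called by camera with the preset correlation, 3, was 2 to 4 under the alternatives run. With an estimated correlation camera called 0 lists under every setting, with 0 to 2 at an unadjusted p below 0.05. Random blocks and robust moderation do not enter camera. For sets as a random block and for robust moderation the list results were therefore those of the main fit, and the lists were not tested under these settings. Of the named genes, upp reversed with median centring (−0.0123), and LBUL_1073 in the control reversed with the median over probes (−0.0911) and in the authors' deposited table (−0.048 after turning the sign). Of 29 named genes called in the chemostat, 17 kept their call without any 1 array. Of the named genes not called in the chemostat, hrcA, pgk, aspS, acpS, valS, ddl, murE, murG, prsA and acpP (LBUL_1294) were called lower, and pheT, atpC, murC and rpmG higher, under at least 1 other setting. With the sample as a random block all of them were called. That fit also took in the control arrays, had no dye term and estimated a correlation within samples of −0.174. The standard error of rpmG was 0.10 there, against 0.19 in the main fit. Calls in that fit are no independent evidence for these genes. Of the 278 chemostat calls with a value in the authors' table, 273 had the same direction there. Sizes there were not set directly against the log2 ratios, since the base of that table is not stated, but only against each other within it. In the authors' deposited table tmk, pyrC and carB (LBUL_1950) had −0.412, −0.408 and −0.405 as mono over mixed and acpP (LBUL_0819) −0.578, so they lay closer to acpP there than in the log2 ratios given above.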

Other observations

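The tests of neighbouring loci and of the predicted open reading frames were chosen before their results were seen; the runs and the array maker's probes were looked at afterwards. For the predicted open reading frames, how a value close to its bound is read was made stricter after the value was known.

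Falls in mixed culture came in runs along the chromosome. Among annotated loci in order of their locus numbers, 37 runs of at least 2 measured neighbours fell together and held 96 loci, and 13 runs with 27 loci rose together. A run of 6 loci starting with LBUL_1668 had a median log2 ratio of −1.27. A run of 3 falling loci ended with the ribosomal protein gene rpmF (median −0.71), and rpsT and rpsO form a falling pair (median −0.80). In the other direction, a run of 3 ended with fabZ (median 1.11).

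Neighbouring loci may change together because they share transcripts. The hypothesis was tested on locus order. Over 1448 pairs of loci with consecutive numbers, the correlation of chemostat log2 ratios was 0.431, while the highest of 10000 shuffled orders gave 0.095 and the control gave −0.018. Both loci were called in the same direction in 68 pairs and in opposite directions in 7; shuffled orders gave a median of 17 same-direction pairs and at most 34. The correlation fits the hypothesis but does not test transcript ends.

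Predicted open reading frames outside the annotation went up more often than down: 7.89% of 431 were called higher and 1.62% lower, against 4.67% and 9.96% of the 1626 annotated loci. Their median log2 ratio was 0.14, against 0.02, a difference of 0.123. Their signal was dimmer (median of the mean log2 signal 7.27, against 8.01). Against annotated loci matched on signal the difference was 0.0639 (0.0476 to 0.0773 over random matches). This range holds only the draw of matches, not the spread over arrays or features. Whether dim signal is the whole cause therefore stays open. The broad signal on chemostat arrays 1, 3 and 7 stays open too: without these arrays the matched difference was 0.0303 (0.0189 to 0.0448), above the bound of 0.03 set beforehand by less than its spread. In the control the matched difference was −0.0278 (−0.0373 to −0.019), a range that also leaves out 0.

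Of the 60 array maker's control probes, 1 was called in the chemostat, a bright corner probe with a log2 ratio of 0.61 (limma adjusted p = 0.0001). In the control its value was 1.46 (adjusted p = 2.5e-13).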
